A study of Homo sapiens with 31 samples.

How the data were processed

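RNA from 31 skin samples was amplified with the NuGEN Ovation V2 system and labelled with the NuGEN Encore biotin module, per the labels' protocols, and hybridised to an Affymetrix oligonucleotide array with 54675 probe sets, each a group of short probes for the 3' part of a transcript. The submitters' processing notes name GCOS, the array maker's software, with no version. The deposited values are intensity on a linear scale, 1 value per probe set and array, made by the authors. On every array the mean of the values between the 2nd and 98th percentile was 499.9, so each array had been scaled to a common trimmed mean, as the values themselves show. The background correction and probe summary behind these intensities are not given in the sources used here. The probe sets report mainly the 3' part of transcripts, and the log2 ratio of the 3' to the 5' beta-actin control probe set was 2.65 ± 0.59 (SD, n = 15) in lesional, 3.01 ± 0.64 (SD, n = 11) in nonlesional and 3.44 ± 1.45 (SD, n = 5) in healthy skin. No 2 arrays held the same values, the highest correlation between 2 arrays being 0.972.

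Groups came from the sample labels: lesional skin (15 arrays), nonlesional skin (11) and healthy skin (5). Lesional and nonlesional samples with the same subject number come from the same person, per the labels, which gives 11 pairs, and 4 lesional samples have no partner. Samples of different subjects are separate donors. The consensus correlation of arrays from the same person about their group means was 0.0248, and 0.194 without the 1 pair whose order on the first principal component was opposite to the other 10. No array date or batch label was used here.

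Values were turned to log2(intensity + 21), the pseudocount being 0.25 of the overall median of 82.4. Array medians differed by 1.55-fold, above the limit of 1.25 set before the data were examined, so the arrays were quantile normalized in limma 3.58.1 (R 4.3.3). Probe sets were named through the platform's annotation, which can be old: 41097 had 1 gene symbol, 1801 several and 11777 none, and only the first kind was used. Of these, 54 had no match to a current gene ID and 0 symbols needed updating. Before any step 99 probe sets for X-inactivation or Y-linked transcripts were removed. Each gene was represented by its probe set with the highest mean, those of the cross-hybridising kind being used only where a gene had no other, which left 19738 genes, of which 10509 had over 1 probe set. The 13728 genes above the overall median (log2 6.69) on at least 5 arrays were tested.

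One limma model with a mean for each of the 3 groups, moderated variances with a trend and no term for the person was fitted to all 31 arrays, and each pair of groups was compared with a two-sided test and Benjamini-Hochberg adjustment over 13728 genes. The 37 gene lists, with 532 genes, were written before the data were examined. They cover cytokine and interferon pathways, granuloma products and markers of the immune, epithelial, gland, muscle, nerve, vascular, fat, pigment and blood cells that skin can hold, and 489 of their genes were on the array under a single symbol. The 36 lists with at least 3 tested members were compared with all other genes by camera at a preset inter-gene correlation of 0.01, adjusted over the lists, and again with an estimated correlation and with fry. The red blood cell list had 1 tested member, HBD, and was not tested. Many list members are also expressed by several cell types of skin, and some genes stand in more than 1 list, so that lists are not independent of each other.

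The genes named in the text follow a rule fixed before the data were examined: in each comparison the 10 largest rises and 10 largest falls among genes past the threshold, up to 4 members of each list with the largest change among its called members (or its largest changes, where none was called), and a set of cytokine and sarcoidosis genes named in advance. Immunoglobulin and T cell receptor segments, HLA-DRB and HLA-DQ genes and sex-linked transcripts are never named. Provisional symbols beginning with LOC, and TARP, were also left out, an exception not written in that rule.

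The procedure was tested on simulated arrays with the real genes' means and spreads, in which 200 of 13728 genes were changed. At 2-fold and 4-fold changes it recovered 84% and 99% for lesional minus nonlesional skin, 69% and 96% for lesional minus healthy skin and 78% and 92% for nonlesional minus healthy skin, with 4, 9 and 10 false calls. In a simulation of lesional minus nonlesional skin the 1 shifted list was recovered and 0 others were called. Genes varied independently in all these simulations. In the data they did not, with an estimated correlation of 0.81 among macrophage and monocyte markers for lesional minus nonlesional skin. False calls among correlated genes, and those of camera at the preset correlation, were therefore not tested.

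Alternatives planned before the data were examined were pseudocounts of 2.1 and 84, no normalization beyond the authors' scaling or centring on the array median, no filter or one at the 75th percentile, the mean of a gene's probe sets, all probe sets, only the 2 groups compared, array weights, no variance trend, the person as a random or fixed block, the pairs without the block, and leaving out each healthy array. Added after the data were seen were fits without the doubted nonlesional array or its pair, the blocked fit without that pair, the actin 3' to 5' ratio as a covariate and the macrophage list mean as a covariate.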

Results

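Gene expression was measured with 31 oligonucleotide arrays on RNA from skin biopsies of 20 people. Cutaneous sarcoidosis is the skin form of a disease in which granulomas, compact clusters of macrophages ringed by T cells, form in affected tissue. Lesional skin was taken from 15 people with active disease, and 11 of them also gave a sample of their own nonlesional skin. Healthy skin came from 5 other people. The study design set lesional skin against both nonlesional and healthy skin, and the remaining comparison, nonlesional against healthy, follows from the same samples. The deposited intensities covered 54675 probe sets on each array, with array medians between 63.3 and 97.9, and the number of arrays limits the precision. Changes below are differences of log2(intensity + 21), which understate the change of dim genes, and errors are standard errors of the difference unless stated. A gene counted as changed at a Benjamini-Hochberg adjusted p under 0.05 in limma over 13728 genes.

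The arrays were ordered mainly along 1 axis. The first principal component carried 51.4% of the variance, with a mean of 38.6 ± 34.7 (SD, n = 15) in lesional skin, -29.2 ± 45.3 (SD, n = 11) in nonlesional skin and -51.5 ± 10.1 (SD, n = 5) in healthy skin. In 10 of the 11 pairs from the same person the lesional array lay higher on it. In the remaining pair, 1 nonlesional array lay beyond every lesional array, and the lesional array of the same person lay inside the range of the other nonlesional arrays. Counts without this pair, called the doubted pair below, are given beside each comparison and were chosen after the data were seen.

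Lesional skin carried far more signal from macrophage genes than nonlesional skin. All 16 tested macrophage and monocyte markers rose, with a median log2 change of 2.01, and the mean of the list was higher in the lesional sample in 9 of 11 pairs. FCGR1A, a high-affinity receptor for IgG, rose by 3.18 ± 0.67, the complement component C1QB by 3.11 ± 0.62, the scavenger receptor MARCO by 2.71 ± 0.53 and the integrin ITGAX by 2.47 ± 0.56. Of 26 tested lysosome, phagocyte and granuloma products, 23 rose, led by the macrophage elastase MMP12 (3.33 ± 0.86, 10.0-fold, adjusted p = 0.00426), the metalloprotease-like ADAMDEC1 (3.01 ± 0.70), the chitinase CHIT1 (3.01 ± 1.00, 8.03-fold, adjusted p = 0.0198) and osteopontin, SPP1 (2.92 ± 0.82). DCSTAMP, needed for the fusion of macrophage-lineage cells, rose by 2.86 ± 0.76 and the secreted phospholipase PLA2G2D by 3.04 ± 0.89. Angiotensin-converting enzyme, ACE, used as a serum marker of sarcoidosis, rose by 1.79 ± 0.36, and CYP27B1, the enzyme that makes active vitamin D, by 2.40 ± 0.61. The chemokine CCL18 rose by 2.09 ± 0.55. Both lists were shifted against all other genes in camera at a preset correlation of 0.01 (adjusted p = 5.27e-11 and 7.71e-10). Neither call held at adjusted p = 0.279 with an estimated correlation.

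**Figure D1:**
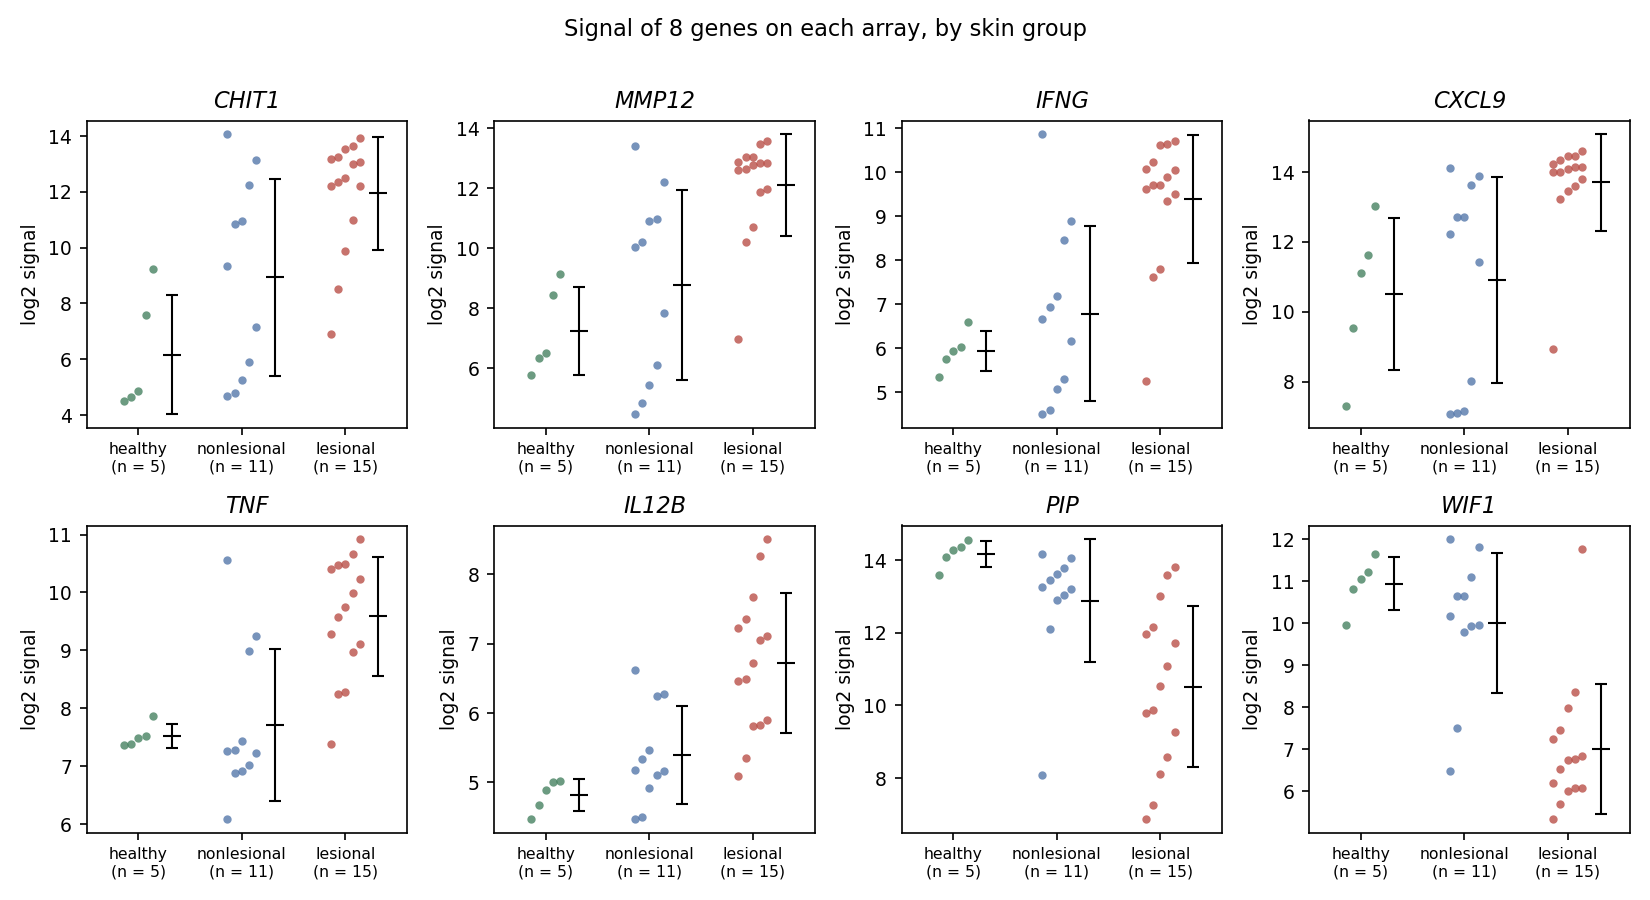
Each point is 1 array's normalized log2(intensity + 21) for the gene in the panel title, by group (healthy n = 5, nonlesional n = 11, lesional n = 15), and the bar beside the points is the group mean ± SD. For MMP12 the mean was 12.09 ± 1.69 in lesional, 8.77 ± 3.15 in nonlesional and 7.24 ± 1.46 in healthy skin, and for WIF1 the order was the opposite.

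T cell and interferon genes rose together with the macrophage genes. Of 19 T cell markers 18 rose (median 1.81), among them CD2 (2.45 ± 0.51), the costimulatory receptor ICOS (2.16 ± 0.46) and CD3D (2.12 ± 0.44). Of 12 cytotoxic and NK cell markers 11 rose (median 1.95), including the granzymes GZMH (2.43 ± 0.59) and GZMB (2.20 ± 0.77). IFN-gamma and Th1 genes rose in 21 of 22 cases (median 1.78), and the list mean was higher in the lesional sample in 10 of 11 pairs. IFNG itself rose by 2.60 ± 0.59 (adjusted p = 0.00187), and its target chemokines CXCL9 and CXCL10 rose by 2.78 ± 0.81 and 2.70 ± 0.72, with the T cell chemokine CCL5 at 2.58 ± 0.53. Type I interferon-stimulated genes rose in 19 of 20 cases (median 1.23), for example OASL (1.86 ± 0.40), OAS2 (1.65 ± 0.32) and IFIT3 (1.48 ± 0.26). Antigen presentation genes rose in 20 of 21 cases (median 1.01), led by the costimulatory ligand CD86 (2.41 ± 0.41), with the lysosomal protease CTSS at 1.73 ± 0.34. The adjusted p of these 5 lists lay between 7.85e-11 and 9.03e-05 at the preset correlation. It was 0.279 with an estimated correlation for 4 of them, and adjusted p = 0.309 with an estimated correlation for the cytotoxic list.

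The IL-12 and IL-23 receptors and signalling genes rose in 7 of 9 tested cases (median 0.95). IL12B, the subunit shared by both cytokines, rose by 1.33 ± 0.32, the shared receptor chain IL12RB1 by 1.99 ± 0.42, IL12RB2 by 1.41 ± 0.29, STAT4 by 1.08 ± 0.29 and IL23R by 0.87 ± 0.30. Of 13 tested Th17 genes 10 rose (median 0.95), led by IL21R (2.54 ± 0.55), KLRB1 (2.03 ± 0.50), IL26 (1.96 ± 0.51) and IL1B (1.85 ± 0.52). The Th17 cytokines IL17A, IL17F, IL21 and IL22, together with IL12A, IL23A and IL10, were too dim to be tested. Of 17 TNF and NF-kappa-B genes 15 rose (median 1.10), with TNF at 1.87 ± 0.40 and the chemokine CCL4 at 2.89 ± 0.59. IL6 rose by 0.98 ± 0.31 and TGFB1 by 1.34 ± 0.26. The adjusted p at the preset correlation was 0.0011, 0.000163 and 6.3e-08 for the IL-12/IL-23, Th17 and TNF lists. For each it was adjusted p = 0.279 with an estimated correlation.

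Other immune lists also shifted upward. Complement genes rose in 10 of 13 cases (median 1.53), with the C5a receptor C5AR1 at 2.37 ± 0.45. Lymphoid organisation genes rose in 8 of 10 cases (median 1.38), among them the B cell chemokine CXCL13 (2.32 ± 0.74), the B cell survival factor TNFSF13B (2.05 ± 0.39), LTB (1.75 ± 0.47) and CCL19 (1.62 ± 0.44). Regulatory T cell and checkpoint genes rose in 7 of 11 cases (median 1.36), with PD-L1, CD274, at 2.44 ± 0.53 and CTLA4 at 2.27 ± 0.46. B cell and plasma cell markers rose in 6 of 12 cases (median 0.98), for example MS4A1 (2.01 ± 0.79) and JCHAIN (1.92 ± 0.68). Dendritic and Langerhans cell markers rose in 8 of 13 cases (median 1.00), with CD83 at 1.78 ± 0.39 and the cross-presenting dendritic cell marker XCR1 at 1.50 ± 0.33. Neutrophil and eosinophil markers rose in 4 of 7 cases (median 1.01), led by FPR1 (2.23 ± 0.49), and IL-17-responsive keratinocyte genes in 4 of 14 (median 0.86), led by CXCL1 (1.87 ± 0.41) and S100A9 (1.57 ± 0.53). Extracellular matrix and remodelling genes rose in 10 of 20 cases and fell in 1 (median 0.40), with MMP9 at 2.68 ± 0.74, TIMP1 at 1.18 ± 0.17 and fibronectin, FN1, at 1.03 ± 0.21. The adjusted p of these lists at the preset correlation ran from 2.27e-06 for complement to 0.0207 for the keratinocyte list. They ran from adjusted p = 0.279 to adjusted p = 0.483 with an estimated correlation.

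Genes of skin appendages, epidermis and smooth muscle fell in lesional skin. Of 11 sweat gland markers 10 fell (median -1.72), including the secretory protein PIP (-2.37 ± 0.70), the secretoglobin SCGB2A1 (-2.20 ± 0.55) and carbonic anhydrase CA6 (-2.19 ± 0.60), and the list mean was lower in the lesional sample in 10 of 11 pairs. Of 11 sebaceous gland markers 7 fell (median -1.10), with KRT79 at -1.85 ± 0.69 and ACSBG1 at -1.69 ± 0.49. Differentiated keratinocyte markers fell in 10 of 19 cases (median -0.70), for example LCE2B (-1.30 ± 0.37), DSC1 (-1.24 ± 0.44) and CASP14 (-1.11 ± 0.35), basal keratinocyte markers in 2 of 8 (KRT15, -1.03 ± 0.30) and hair follicle markers in 3 of 12 (LGR5, -1.79 ± 0.46, and KRT31, -1.32 ± 0.38). The mean of the differentiated keratinocyte list was lower in the lesional sample in 8 of 11 pairs and higher in 3. Smooth muscle and pericyte markers fell in 6 of 10 cases (median -0.65), with CNN1 at -1.20 ± 0.27 and LMOD1 at -1.14 ± 0.28. WNT and hedgehog genes fell in 7 of 14 cases and rose in 1 (median -0.48). The WNT inhibitor WIF1 had the largest fall of all named genes (-3.00 ± 0.57, 8.00-fold lower, adjusted p = 0.000689), and the hedgehog receptor PTCH1 was at -0.95 ± 0.15 and SOSTDC1 at -1.25 ± 0.38. Outside the lists, CRISP3 (-2.53 ± 0.69), PM20D1 (-2.35 ± 0.87) and the anti-inflammatory cytokine IL37 (-2.13 ± 0.40) were among the 10 largest falls. These 7 lists had adjusted p between 0.000173 and 0.0276 at the preset correlation. The range was adjusted p = 0.282 to adjusted p = 0.493 with an estimated correlation.

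In all, 5174 genes changed between lesional and nonlesional skin, 2562 up and 2612 down (2621 up and 1887 down with each array centred on its median), and 827 rose and 374 fell at least 2-fold. Without the doubted nonlesional array 1058 rose and 699 fell at least 2-fold, and without the pair 1145 and 795. Of 36 lists tested 25 shifted, 18 up and 7 down, none of which held with an estimated correlation, while 24 passed fry, which asks only whether a list's genes moved on balance in 1 direction. Of the shifted lists, the IL-17-responsive keratinocyte, sebaceous gland and hair follicle lists missed the threshold in fry (adjusted p = 0.0571). With the 11 pairs alone and each person as a block, 2460 genes changed, and the same pairs without the block gave 3514. The doubted pair set that number, since the blocked count was 6728 without it, and 6836 genes changed in the fit over all other arrays. Of 98 genes named for this comparison, 34 lost their call in the blocked fit over 11 pairs: CHIT1, PLA2G2D, DCSTAMP, IL12B, IL23R, STAT4, IL1B, CXCL13, CCL19, LTB, MS4A1, JCHAIN, CYP27B1, PIP, CA6, KRT79, ACSBG1, LCE2B, CASP14, DSC1, KRT15, KRT31, SOSTDC1 and PM20D1 above and 10 named under other observations. Over the pairs without the doubted one none of the 98 lost its call. That pair was set aside because it ran opposite to the others, and leaving it out by itself favours these calls. The value is thus no independent support for them. The basal keratinocyte list also lost its call in the blocked fit over 11 pairs, and the B cell, dendritic cell, IL-17-responsive keratinocyte, sebaceous gland and hair follicle lists did with a filter at the 75th percentile. The IL-17-responsive keratinocyte list lost its call also with array weights and without the doubted nonlesional array, the hair follicle list with array weights and the basal keratinocyte list over the 11 pairs without the block. Adjusted over the list alone, counts differed for lysosome, phagocyte and granuloma products (24 up, 1 down), complement (11 up, 1 down), extracellular matrix (13 up, 1 down), IFN-gamma and Th1 (21 up, 1 down), regulatory T cell (7 up, 1 down), dendritic cell (9 up, 1 down), Th17 (11 up), B cell (7 up), neutrophil (5 up), sweat gland (11 down), smooth muscle (8 down) and WNT and hedgehog genes (1 up, 8 down).

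Against healthy skin, lesional skin carried most of the immune lists at higher levels and the gland lists at lower levels. CHIT1, dim in healthy skin, rose by 5.78 ± 1.30 (adjusted p = 0.00116, log2 change 4.67 to 7.00 across settings), MMP12 by 4.85 ± 1.12 MMP9 by 4.65 ± 0.97, PLA2G2D by 4.30 ± 1.16, and the C-type lectin CLEC4E and DCSTAMP each by 4.46, with errors of 0.98 and 0.99. All 16 macrophage and monocyte markers rose (median 2.87), with C1QB at 4.15 ± 0.81, and 23 of 26 lysosome, phagocyte and granuloma products did (median 1.99). All 20 type I interferon-stimulated genes rose (median 1.80), led by EPSTI1 (3.15 ± 0.40), IFI27 (2.63 ± 0.34) and CMPK2 (2.58 ± 0.40). IFN-gamma and Th1 genes rose in 21 of 22 cases (median 2.58), with CXCL10 at 3.98 ± 0.94, the tryptophan-degrading enzyme IDO1 at 3.89 ± 0.85, GBP5 at 3.51 ± 0.82 and IFNG at 3.45 ± 0.77. Antigen presentation genes rose in 20 of 21 cases (median 1.92), T cell markers in 18 of 19 (median 2.06), TNF and NF-kappa-B genes in 15 of 17 (median 1.76) and complement genes in 11 of 13 (median 2.02). CD80 rose by 3.23 ± 0.58, CD86 by 3.21 ± 0.53, CD2 by 2.81 ± 0.66, CD4 by 2.62 ± 0.49, CCL4 by 3.40 ± 0.77, TNF by 2.06 ± 0.53, TGFB1 by 2.06 ± 0.33, IL6 by 2.37-fold, CCL18 by 2.54 ± 0.72, ACE by 2.10 ± 0.47 and CYP27B1 by 3.87 ± 0.80. The adjusted p of these 8 lists was at most 1.34e-06 at the preset correlation. With an estimated correlation it lay between adjusted p = 0.27 and adjusted p = 0.32.

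Several smaller immune lists followed. IL-12 and IL-23 genes rose in 7 of 9 cases, with IL12RB1 at 2.76 ± 0.54, IL12B at 1.91 ± 0.42, JAK2 at 1.81 ± 0.32, IL12RB2 at 1.76 ± 0.38 and IL23R at 1.07 ± 0.39, and Th17 genes in 8 of 13 (largest change 2.87). Cytotoxic and NK cell markers rose in 10 of 12 cases and fell in 1 (median 2.30), with GZMH at 3.42 ± 0.77 and GZMB at 3.39 ± 1.00. Lymphoid organisation genes rose in 8 of 10 cases (median 1.86), and regulatory T cell and checkpoint genes rose in 7 of 11 and fell in 1 (median 1.96, CD274 at 3.14 ± 0.69). Dendritic and Langerhans cell markers rose in 8 of 13 cases and fell in 2 (median 1.17), extracellular matrix genes rose in 9 of 20 and fell in 1 (median 0.62), and B cell and plasma cell markers rose in 1 of 12 (median 0.92). The adjusted p of these 8 lists at the preset correlation ran from 0.000456 to 0.0444. The same lists had adjusted p = 0.27 to adjusted p = 0.614 with an estimated correlation. The B cell list, unlike the others, missed the threshold in fry (adjusted p = 0.14). Neutrophil and eosinophil, IL-17-responsive keratinocyte, Th2 and mast cell lists missed the threshold in camera at the preset correlation. Of these, the neutrophil and keratinocyte lists had shifted upward against nonlesional skin.

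Gland markers fell from healthy to lesional skin. All 11 sweat gland markers fell (median -2.64), including PIP (-3.66 ± 0.91), SCGB2A1 (-3.27 ± 0.72), the water channel AQP5 (-2.96 ± 0.81) and KRT77 (-2.87 ± 0.59), and 10 of 11 sebaceous gland markers fell (median -2.27), including KRT79 (-3.04 ± 0.90) and ELOVL3 (-2.87 ± 0.78). WNT and hedgehog genes fell in 8 of 14 cases (median -0.79), with WIF1 at -3.93 ± 0.74, SOSTDC1 at -2.32 ± 0.50 and SFRP1 at -2.19 ± 0.47. Hair follicle markers fell in 3 of 12 cases (KRT31, -2.25 ± 0.50), basal keratinocyte markers in 2 of 8 (KRT15, -1.63 ± 0.40) and lipid and cholesterol synthesis genes in 4 of 13 (FASN, -1.37 ± 0.38, and DHCR7, -1.35 ± 0.29). The largest falls of named genes were the steroid-conjugating enzyme UGT2B28 (-6.20 ± 0.58), DHRS2 (-4.89 ± 0.72), the anion exchanger SLC26A3 (-4.60 ± 0.58), PM20D1 (-4.21 ± 1.13) and the salivary-type mucin MUC7 (-4.11 ± 0.61). The adjusted p of these 6 lists ran from 6.03e-05 to 0.0458 at the preset correlation. With an estimated correlation it ran from adjusted p = 0.27 to adjusted p = 0.471.

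In all, 5113 genes changed between lesional and healthy skin, 2503 up and 2610 down (2697 up and 1936 down with each array centred on its median), and 1168 rose and 933 fell at least 2-fold. Without the doubted pair the count was 5884. Of 36 lists 22 shifted, 16 up and 6 down, none of which held with an estimated correlation, and 24 passed fry. CXCL9 (3.19 ± 1.06, adjusted p = 0.0187) lost its call when either of 2 healthy arrays was left out, and LCN2 (-2.10 ± 0.62, adjusted p = 0.00895) and IL6 lost theirs without 1 of them, while IL23R lost its call without each of 3 healthy arrays. The B cell, lipid and cholesterol synthesis, dendritic cell and hair follicle lists lost their calls with 1 or more healthy arrays left out, and the B cell and dendritic cell lists also with each array centred on its median. With a filter at the 75th percentile the B cell, dendritic cell and hair follicle lists lost their calls, and with the actin 3' to 5' ratio as a covariate the B cell, dendritic cell and lipid and cholesterol synthesis lists. Adjusted over the list alone, 25 lysosome, phagocyte and granuloma products and 8 regulatory T cell and checkpoint genes rose, and 0 B cell markers.

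**Figure D2:**
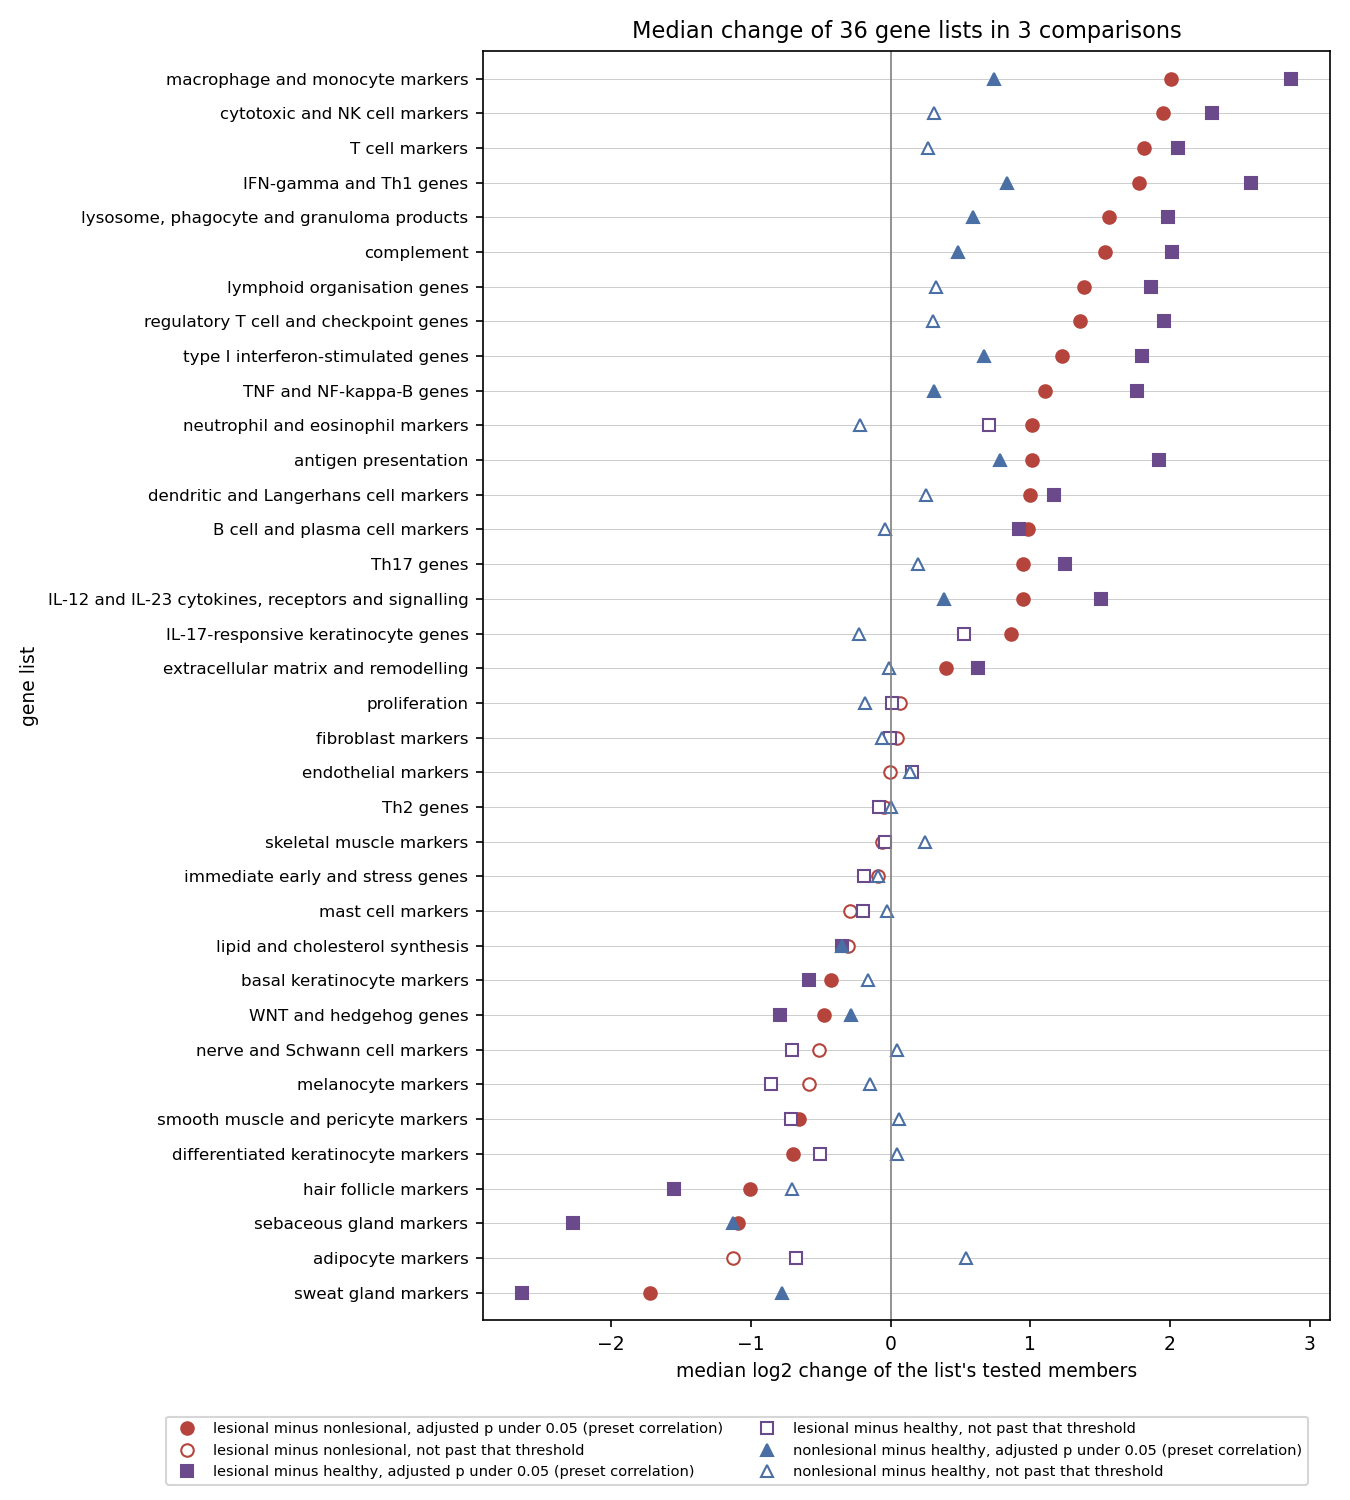
Each marker gives the median log2 change of the tested members of 1 of 36 gene lists (rows) in 1 of the 3 comparisons (shape), filled where camera with the preset correlation gave an adjusted p under 0.05. Macrophage markers stand at 2.01, 2.87 and 0.74 in the order lesional minus nonlesional, lesional minus healthy and nonlesional minus healthy, and sweat gland markers at -1.72, -2.64 and -0.78.

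The 2 lesional comparisons shared 1953 rising and 1702 falling genes, and 2 genes changed in opposite directions. Independent lists of the same sizes would share 467 and 497. Both comparisons use the same lesional arrays, so their calls are not independent. With the lesional arrays divided, 8 set against nonlesional and the other 7 against healthy skin, 1253 rising and 779 falling genes were shared, where independent lists would share 291 and 264, and 8 genes changed in opposite directions. This was a single random division. Both comparisons came from the same fit, with the same spread for each gene, so their calls were still not fully independent.

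Few genes passed the threshold between nonlesional and healthy skin, with 11 and 5 arrays. At an unadjusted p under 0.05 in limma there were 1607 of 13728. Of 58 genes that changed 49 fell, 36 of them at least 2-fold, and 9 rose, while with array weights 54 rose and 96 fell. The largest falls were UGT2B28 (-5.91 ± 0.61, adjusted p = 7.9e-07), the reductase DHRS2 (-4.33 ± 0.75), SLC26A3 (-4.07 ± 0.61), the iron-binding secretory protein lactoferrin, LTF (-3.88 ± 0.68, 14.7-fold lower, adjusted p = 0.00418), the medium-chain acyl-CoA synthetases ACSM1 (-3.78 ± 0.55) and ACSM3 (-2.67 ± 0.54), MYBPC1 (-2.92 ± 0.50), SERHL2 (-2.91 ± 0.61), the histone gene H2AC8 (-2.49 ± 0.49) and the paraoxonase PON3 (-2.45 ± 0.50). All 5 healthy arrays lay above all 11 nonlesional arrays for UGT2B28, LTF and ACSM1, an order that 1 of the 4368 splits of these arrays gives for any gene, and these genes were picked on the same arrays as the largest falls. The gap was narrow for UGT2B28 (lowest healthy 7.99, highest nonlesional 7.97) and ACSM1 (6.92 and 6.88) and wider for LTF (11.10 and 9.42). For DHRS2, SERHL2, H2AC8 and PON3, 4 healthy arrays lay above all nonlesional arrays, for SLC26A3 and MYBPC1 3, and for ACSM3 2. Healthy arrays spread from 7.99 to 14.27 for UGT2B28 and from 4.54 to 13.19 for DHRS2. The eosinophil chemokine CCL26 fell by 1.52 on the log2 scale (SE 0.33). Of the 9 rises 2 were at least 2-fold. KRT2, a keratin of the upper epidermis, rose by 0.85 ± 0.20, ST7-AS1 by 1.05 ± 0.24, SAMD4A by 0.77 ± 0.17, RAP2C by 0.55 ± 0.11, PTP4A1 by 0.50 ± 0.12, the methyl-DNA-binding protein MBD2 by 0.44 ± 0.07, RRAGC by 0.36 ± 0.07 and TSNAX by 0.29 ± 0.05.

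**Figure D3:**
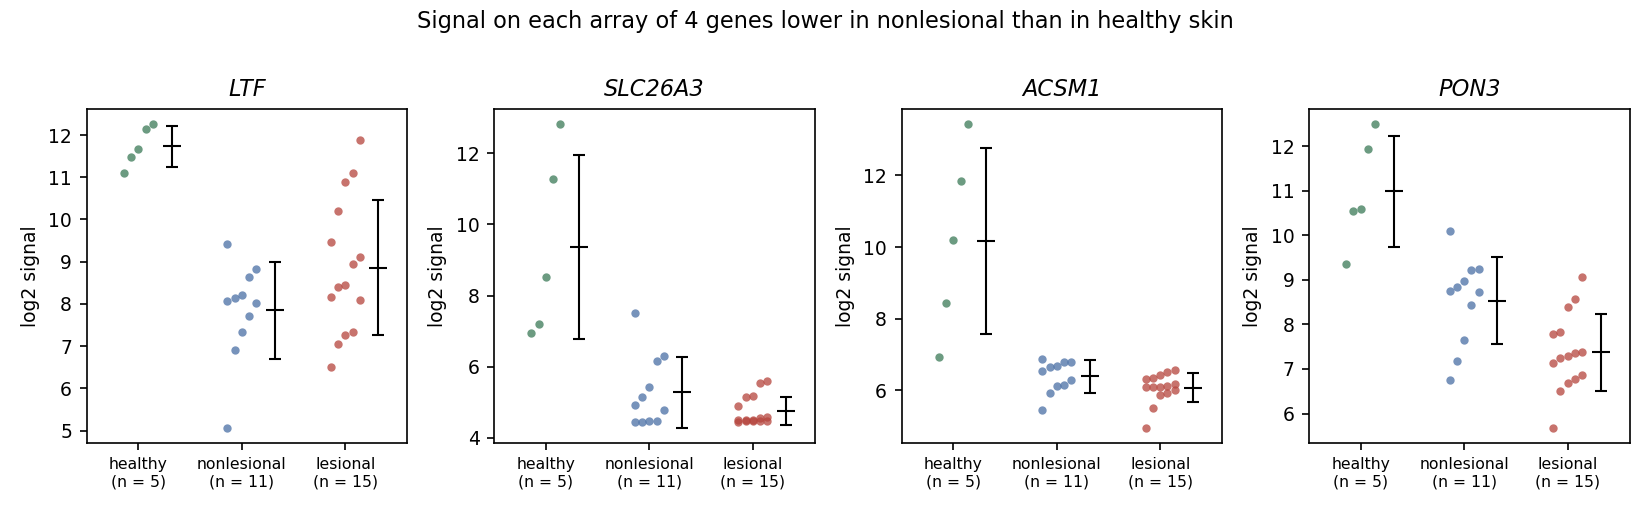
Each point is 1 array's normalized log2(intensity + 21) for the gene in the panel title, by group (healthy n = 5, nonlesional n = 11, lesional n = 15), with the group mean ± SD beside it. The lowest healthy LTF value was 11.10 and the highest nonlesional value 9.42, while the healthy arrays for SLC26A3 spread from 6.95 to 12.82.

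List medians between nonlesional and healthy skin were positive for 8 immune lists and negative for 4 others, by calls that rest on the preset correlation alone. Medians were 0.83 for IFN-gamma and Th1 genes, 0.79 for antigen presentation, 0.74 for macrophage and monocyte markers, 0.67 for type I interferon-stimulated genes, 0.59 for lysosome, phagocyte and granuloma products, 0.48 for complement, 0.38 for IL-12 and IL-23 genes and 0.31 for TNF and NF-kappa-B genes. They were -1.12 for sebaceous gland markers, -0.78 for sweat gland markers, -0.35 for lipid and cholesterol synthesis and -0.29 for WNT and hedgehog genes. None of the members of these 12 lists was called over all genes, while 5 type I interferon-stimulated genes, 4 antigen presentation genes, 1 Th1 gene and 1 complement gene passed when adjusted over the list alone. The granuloma products and cytokines varied widely between nonlesional arrays. CHIT1 stood at 2.77 ± 1.36 (adjusted p = 0.428), MMP12 at 1.53 ± 1.17 (adjusted p = 0.655), CXCL10 at 1.29 ± 0.98 (adjusted p = 0.652), IFNG at 0.85 ± 0.81 (adjusted p = 0.733), CXCL9 at 0.40 ± 1.11 (adjusted p = 0.923), ACE at 0.32 ± 0.49 (adjusted p = 0.853) and TNF at 0.20 ± 0.55 (adjusted p = 0.926). Further values that missed the threshold were MMP9 at 1.97 ± 1.01, CYP27B1 at 1.47 ± 0.83, IL12RB1 at 0.77 ± 0.57, TGFB1 at 0.73 ± 0.35, IL12B at 0.58 ± 0.44, CCL18 at 0.45 ± 0.75, IL12RB2 at 0.35 ± 0.40, IL6 at 0.27 ± 0.42 and IL23R at 0.20 ± 0.41. The 12 lists had adjusted p between 3.32e-09 and 0.0371 at the preset correlation. With an estimated correlation none passed (adjusted p = 0.838 to adjusted p = 0.852), and fry passed 0 of 36 lists, with the type I interferon list at adjusted p = 0.461 in fry.

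The count of 58 changed with the arrays in the fit. It was 15 without 1 healthy array, 20 without another and 61 to 75 without each of the other 3, and 12 of the 58 genes were called in all 5 of these fits: ACSM1, DHRS2, FOXE1, GLYATL2, LTF, MBD2, MMP7, MYBPC1, RAP2C, SLC26A3, TSNAX and UGT2B28, of which FOXE1, GLYATL2 and MMP7 are named only after their values were seen. With these 2 groups alone in the fit 5 genes changed, UGT2B28, LTF, MMP7 and GLYATL2 downward and MBD2 upward, and without the doubted pair 54 did. Of the 12 lists, IL-12 and IL-23, lipid and cholesterol synthesis, complement, sebaceous gland, sweat gland and WNT and hedgehog each lost its call without 1 or more single healthy arrays, and the TNF and NF-kappa-B, IL-12 and IL-23 and sweat gland lists lost theirs without the doubted pair, where differentiated keratinocyte and adipocyte markers were added. Without the doubted nonlesional array alone 8 lists shifted, 7 up and 1 down, against 8 up and 4 down with it, and the sweat gland, WNT and hedgehog, lipid and cholesterol synthesis, complement, IL-12 and IL-23 and TNF and NF-kappa-B lists lost their calls. With the macrophage list mean as a covariate 9 of the 12 lost theirs, and 4 did with array weights (sebaceous gland, sweat gland, lipid and cholesterol synthesis, IL-12 and IL-23).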

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

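Of the tests in this part, the comparison of list means for exchanged labels was written after the result was seen, as were the counts of arrays nearer the other group, and the test with the GAPDH ratio was written before its value was computed.

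A gap rule for groups of 4 to 10 samples was applied to 175 values in healthy skin (n = 5), the only group small enough, where 1 array was set apart if its distance to the next exceeded 0.71 of the range. Chance alone sets apart about 1 group in 20, and 6 of 175 were found. CRISP3 was low on 1 healthy array (6.53, next 9.55, gap 0.797 of the range). LYVE1 was low on 1 healthy array (6.59, next 8.56, gap 0.815). EGR1 was low on 1 healthy array (13.09, next 13.48, gap 0.725). CD80 was low on 1 healthy array (4.49, next 5.33, gap 0.717). The log2 ratio of the 3' to the 5' GAPDH probe set was high on 1 healthy array (1.53, next 0.82, gap 0.759). The mean of the melanocyte markers was low on 1 healthy array (10.12, next 10.61, gap 0.735).

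Another array stood apart outside that rule: 1 nonlesional array lay beyond every lesional array on the first principal component, the only pair of 11 in this order. If its label had been exchanged with that of the lesional array of the pair, that lesional array should lie inside the range of the other nonlesional arrays, and it did so on 5 of 5 list means, although it also lay inside the range of the other lesional arrays on 4 of 5. Over the 6836 genes called without the pair, 2 of 2 arrays of the pair were nearer the other group's mean at most genes, against 1 of 14 other lesional and 0 of 10 other nonlesional arrays, though these shares can lie close to an even split. The genes were called from those other arrays, which also form the group means. Their nearness to their own group was thus largely fixed in advance, and they are no fair reference for the pair. RNA quality was tested with a linear trend on the GAPDH ratio over the other nonlesional and the healthy arrays. Only the doubted nonlesional array was compared with the upper 95% prediction limit. Its first principal component value of 89.0 lay above the limit of 31.3, which argues against that trend as the cause. But this array had the highest ratio of all 31, outside the range of the 15 arrays in the trend, so an effect of RNA quality that is not linear stays open. Exchanged labels may account for this pair but are not shown, and infiltrated skin sampled as nonlesional, the biological alternative, was not tested.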

How the results depend on the processing

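The fits without the doubted array or pair and those with the actin ratio or the macrophage mean as a covariate were chosen after the data were seen, and no named gene or list reversed its direction past the threshold where single results were compared. Between lesional and nonlesional skin 5174 genes changed in the main fit. The blocked fit over 11 pairs gave 2460 (1317 up, 1143 down), of which 2338 were among the 5174, and lost no list but basal keratinocyte markers. The same block without the doubted pair gave 6728, and the person as a random block 5255 and, for the healthy comparisons, 5106 and 58. No paired analysis was possible because healthy samples came from other people, so the block in those comparisons rests on the lesional and nonlesional arrays. Without the doubted nonlesional array the counts were 6534, 5548 and 46, with 8 lists in place of 12 between nonlesional and healthy skin, and with the actin ratio 5552, 5322 and 78 (20 up, 58 down). Testing all probe sets gave 10403, 10196 and 122, as more units are tested. With the macrophage list mean as a covariate 0 genes were left between lesional and nonlesional skin (limma, 929 at an unadjusted p under 0.05), 32 between lesional and healthy and 70 (23 up, 47 down) between nonlesional and healthy skin, and 7, 6 and 5 lists, the last after 9 were lost and 2 gained. Of the lesional calls 1376 and 1352 then changed sign. That covariate is itself raised in lesions, so only counts are given for it there. With an estimated correlation 0 lists shifted in each comparison, and fry left 0 lists between nonlesional and healthy skin. Nonlesional minus healthy skin, 58 genes, was the gene count that moved most under the settings chosen before the data were examined: 34 with a pseudocount of 2.1, 114 with 84, 35 with each array centred on its median, 19 with a filter at the 75th percentile, 5 with only the 2 groups compared and 150 (54 up, 96 down) with array weights, and the cause was not tested. Leaving out each healthy array gave 15 to 75 genes and 10 to 12 lists there, and 4234 to 4578 genes and 20 to 24 lists for lesional minus healthy skin. Of 98 genes named for lesional minus nonlesional skin, 34 lost their call in the blocked fit, 19 over the same pairs without the block and at most 5 under each other setting compared gene by gene, which leaves out the macrophage covariate, where no gene passed. Named genes not tested under a setting were left out and could not count as lost. With the filter at the 75th percentile 82 of the 98 were compared, and with the mean of a gene's probe sets 95. Of the 58 genes, 2 were kept under all 16 settings fixed before the data were examined and compared gene by gene, which leaves out the test of all probe sets. Among the 58, a gene not tested under a setting counted as not kept. With the filter at the 75th percentile 31 of the 58 were tested, and with the mean of a gene's probe sets 51. Dim genes limit all counts, since 13728 of 19738 genes passed the filter and the rest were not tested.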

Other observations

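Of the tests in this part, that of dilution of all resident cells alike was written after the result was seen, and the others were written before their values were computed.

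Stromal, vascular and Th2 lists were not shifted between lesional and nonlesional skin, although single members changed. Fibroblast markers rose in 3 of 15 cases and fell in 1 (median 0.05, adjusted p = 0.636 in camera), with THY1 at 1.53 ± 0.25 and FAP, a protease of activated fibroblasts, at 0.96 ± 0.24. Endothelial markers rose in 3 of 15 and fell in 1 (median -0.00, adjusted p = 0.652), with the leukocyte adhesion receptor VCAM1 at 1.30 ± 0.27 and the lymphatic marker LYVE1 at -0.86 ± 0.34, and 2 rose adjusted over the list alone. Th2 genes rose in 3 of 8 and fell in 1 (median -0.04, mean 0.22, adjusted p = 0.636), with the chemokine CCL17 at 1.67 ± 0.40, IL4R at 1.01 ± 0.22 and GATA3 at -0.85 ± 0.21. Proliferation genes rose in 2 of 16 cases (median 0.07, adjusted p = 0.157), AURKA by 0.70 ± 0.19 and BUB1 by 0.61 ± 0.21. Lipid and cholesterol synthesis genes rose in 1 of 13 and fell in 2 (median -0.31, adjusted p = 0.267), with DHCR7 at -0.67 ± 0.22, HMGCS1 at -0.51 ± 0.18 and SREBF1 at 0.40 ± 0.16, and 0 rose adjusted over the list alone, SREBF1 passing over all genes in 7 of the 13 settings, the reported one included, that were chosen in advance for it. Immediate early and stress genes rose in 3 of 12 and fell in 2 (median -0.09, adjusted p = 0.834), with ATF3 at 0.79 ± 0.19 and EGR1 at -0.51 ± 0.13.

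Lists of minor resident cells had negative medians and missed the threshold in camera, while nerve and Schwann cell markers (adjusted p = 0.00705) and melanocyte markers (adjusted p = 0.0494) passed it in fry. In the blocked fit without the doubted pair 11 lists fell in place of 7, the adipocyte, nerve, melanocyte and mast cell lists being added. Adipocyte markers fell in 2 of 8 cases (median -1.13, adjusted p = 0.0687), GPD1 at -1.56 ± 0.47 and PCK1 at -1.10 ± 0.43, with 1 fall adjusted over the list alone. Nerve and Schwann cell markers fell in 2 of 6 (median -0.51, adjusted p = 0.0786), SCN7A at -1.65 ± 0.33 and CDH19 at -1.28 ± 0.29. Melanocyte markers rose in 1 of 8 and fell in 1 (median -0.58, adjusted p = 0.0865), MITF at 0.43 ± 0.16 and OCA2 at -1.30 ± 0.32, with 5 falls adjusted over the list alone. Mast cell markers fell in 1 of 8 (median -0.29, adjusted p = 0.215), KIT at -0.87 ± 0.26, and skeletal muscle markers in 0 of 4 (median -0.06, adjusted p = 0.824), where ACTA1 stood at -0.96 ± 0.40 (adjusted p = 0.0552). In the blocked fit over 11 pairs LYVE1, CCL17, GATA3, DHCR7, HMGCS1, SREBF1, ATF3, MITF, OCA2 and KIT lost their calls. Against healthy skin, CCL26 (-1.91 ± 0.31) and the melanocyte genes SOX10 (-1.45 ± 0.41) and MLANA (-1.40 ± 0.45) fell in lesional skin, where the melanocyte list missed the threshold (adjusted p = 0.114).

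The genes that fell in nonlesional against healthy skin could reflect less gland tissue in the samples. None of the 49 stood in the gland lists, yet their median correlation with the mean of 22 gland markers within groups was 0.31, at the 99.99 percentile of 10000 random sets (median 0.03, 95th percentile 0.167). The random sets were matched on mean signal only, while the 49 genes were picked together on these arrays and may vary together. Sets of unrelated genes vary less in this value, so the percentile overstates the evidence. The 16 arrays also include the doubted nonlesional array, and the value without it was not computed. Of the median change of -1.51, 90.6% was kept with the macrophage mean as a covariate and 100.9% with the actin ratio. These values argue against dilution by infiltrating cells and against RNA quality, as far as a linear trend on each measure can show. They exclude neither, since the groups differed little on both measures. The macrophage mean was 9.56 ± 1.36 (SD) in nonlesional and 8.86 ± 0.70 in healthy skin, and the log2 actin ratio 3.01 ± 0.64 and 3.44 ± 1.45. Disease outside the lesions, the biological alternative, predicts no value here and was not tested.

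In lesional against nonlesional skin sweat gland markers fell and fibroblast markers did not, so an equal dilution of all resident cells by infiltrate may be asked about. The sweat gland change minus the fibroblast change was -1.80 (95% interval -2.88 to -0.71, with the arrays taken as unpaired), which argues against equal dilution as the whole cause, with the reserve that these 2 lists were compared because they had been seen to move apart. Of the 15 fibroblast markers 3 rose and 1 fell. A rise of fibroblast genes on top of equal dilution could give the same difference, so the value does not exclude dilution as a part. Without the doubted pair the difference was -2.27 (-3.15 to -1.38), so it does not rest on that pair, although exchanged labels would be expected to shrink it and this value is no test of the exchange itself. Loss of glands in lesions and sampling of skin with fewer glands were not separated.

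The number of genes changed was compared with 100 splits of the same arrays, the real one included. For lesional minus nonlesional skin 1 split gave as many genes (the next gave 3912), and for lesional minus healthy skin 1 (the next gave 18). For nonlesional minus healthy skin 3 splits gave as many. The highest other split gave 431 genes, several times 58, while the median of the other splits was 0. What the split with 431 genes separates was not examined, and the cause of its count was not tested. Of 100 exchanges of labels within pairs, 2 gave as many genes as lesional minus nonlesional skin, the highest other 5506, with 3 pairs exchanged, the doubted one among them.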
